A study of Mus musculus with 3 samples.

How the data were processed

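RNA sequencing was done on total RNA of mouse embryonic stem cells of the 46C line (strain 129), kept in serum and leukemia inhibitory factor (LIF) on gelatin. The 46C line carries a fluorescent reporter at the Sox1 locus. Per the labels, 1 culture had received an empty vector and was collected at passage 2, and cultures that had received Lef1 were collected at passage 2 and at passage 5. These 3 libraries are called empty vector P2, Lef1 P2 and Lef1 P5. There is 1 library per group and no replicate, so no test between conditions was made and no p-value is given. Intervals cover counting error only, apart from a bootstrap interval for GC content.

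Per the file headers, each library has 1 gene table with an Entrez gene number, RefSeq transcripts, a length, an expected count and an FPKM value (fragments per kilobase of transcript, scaled to the library). The deposited expected counts need not be whole numbers: they were not whole in 8.61% of the listed genes of empty vector P2, 8.56% of Lef1 P2 and 8.49% of Lef1 P5. How reads that match several genes were counted is not given in the sources used here. Not every named gene with such counts is marked in the text, for example Akr1b3, Snrpn, Lefty2 and Nanog. The counting program and whether counting used strand are not given in the sources used here. Per the submitters' processing notes, Bowtie 0.12.2 and the mm8 build were used. The tables as deposited list genes with a value above 0, down to 0.01 FPKM, so a gene missing from a library was taken as 0. The expected counts summed to 9225401 in empty vector P2, 9170554 in Lef1 P2 and 9380813 in Lef1 P5, and 16450, 16916 and 16587 genes were listed. At this depth 3 reads on a transcript of 1 kb amount to 0.325, 0.327 and 0.320 FPKM.

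Gene symbols came from a RefSeq gene table of GRCm38 through the Entrez numbers, and 17951 of 17997 numbers matched. The build differs from mm8, so the reference served only for names, for transcript base composition and for which genes are neighbours, and no coordinates are given. No symbol occurred in more than 1 row.

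The FPKM values were used as deposited. For each comparison the ratio was log2((x + 1)/(y + 1)) with a pseudocount of 1 FPKM, which understates the change of weakly expressed genes. A gene was called higher or lower when this ratio was at least 1 in size (2-fold), with at least 3 FPKM and at least 20 expected reads in the higher library. Folds in the text are plain ratios of FPKM values, except where the log2(FPKM + 1) scale is named. Where a gene was not listed in a library, the fold is a lower bound against 3 reads in that library. Exact Poisson 95% intervals were computed from the expected counts and put on the FPKM scale. Amplified reads without molecular identifiers are not independent molecules, and these intervals leave out that source of error as well as the difference between cultures.

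A set of 23 gene lists was fixed before the data were examined: core and naive pluripotency, formative and primed epiblast, primitive streak, mesoderm, endoderm, neuroectoderm, trophectoderm, beta-catenin/TCF targets, Wnt pathway components, LIF/STAT3 and BMP/ID targets, 2-cell-like genes, germline genes, cell cycle, p53 targets, fibroblast and feeder-cell genes, cell adhesion and epithelial-mesenchymal genes, imprinted genes, glycolysis and hypoxia, stress and unfolded protein response, replication-dependent histones, ribosomal proteins, oxidative phosphorylation, and long transcripts as a check on RNA integrity. Members that reached 1 FPKM in any library were counted as measured. The list's median log2 ratio is given relative to the median of all 12894 measured genes. Its percentile is its place among 10000 random lists of the same size drawn from 20 bins of mean expression, and a list under 2.5 or above 97.5 is said to stand apart. The percentile describes these libraries and is not a test. The genes named in the text were also chosen by a rule fixed before the data were examined: Lef1, the 8 highest and 8 lowest ratios among called genes, up to 2 highest and 2 lowest called members of each list that stood apart or had at least 3 called members, and 18 genes of the Wnt pathway and pluripotency whatever their values. Names outside this rule were chosen after their values were seen, as examples of a list's called members or to name small counts.

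The comparisons were Lef1 P2 against empty vector P2, Lef1 P5 against empty vector P2, and Lef1 P5 against Lef1 P2. The overlap between the comparisons with the shared empty-vector library was set beside 1000 draws in which the 3 values of each gene were swapped among the libraries, and beside the overlap of independent lists. Counting noise alone was drawn 100 times for unchanged libraries. The alternatives were pseudocounts of 0.1 and 5, minimum levels of 1 and 10 FPKM and no minimum, median-of-ratios, TMM (trimmed mean of M values) and quantile rescaling, fold thresholds of 1.5 and 4, non-overlapping counting intervals, the mean of list members, and members measured at 3 FPKM. Expected counts scaled to the library total (CPM) and the endoderm list without members of other lists were added after the data were seen. The design fixed in advance named values normalized as deposited, with CPM if the files hold counts. These files hold both. The FPKM values stayed the main measure, although this wording can be read as asking for CPM. The choice matters for the calls. With CPM 1225 genes were higher and 281 lower in Lef1 P2 than in empty vector P2, against 691 and 194 with FPKM. Between the Lef1 libraries CPM gave 272 and 1275, against 199 and 727. The values of 2 genes are not reported here.

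The rule for calls was tested on simulated counts for 17997 genes with 200 genes changed by known folds. The changed genes were drawn only from genes well above the minimum level and read count of the rule. In the simulated comparison of Lef1 P2 with empty vector P2, 100% of the genes changed 3-fold or 6-fold were called. Of those changed 1.5-fold 0% were called, and of the unchanged genes 0 of 17797. The simulated counts held Poisson counting noise only, without differences between cultures or library preparations. They therefore give no rate of false calls between cultures. At such levels the shares of changed genes called follow largely from the 2-fold threshold, and weakly expressed genes were not covered. Of 400 random lists of 25 genes, 6.25% stood apart in the deposited, not simulated, values of Lef1 P2 against empty vector P2. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.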

Results

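RNA-seq was used to ask how the transcripts of mouse embryonic stem cells differ when Lef1, a DNA-binding partner of beta-catenin in Wnt signalling, is introduced. Each of the 3 groups (empty vector P2, Lef1 P2 and Lef1 P5) has n = 1 library, with 9225401, 9170554 and 9380813 expected counts. With no replicates, the comparisons below describe these libraries, and genes are called higher or lower by size alone. Intervals in parentheses are 95% counting intervals unless named otherwise. Across genes, which are not independent replicates, Spearman's rho of the FPKM values was 0.964 between empty vector P2 and Lef1 P2, 0.975 between empty vector P2 and Lef1 P5 and 0.967 between the Lef1 libraries.

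Lef1 itself (Entrez gene 16842) was at 1.49 FPKM (1.10 to 1.98) in empty vector P2, 135 FPKM (131 to 139) in Lef1 P2 and 214 FPKM (208 to 219) in Lef1 P5. This is 90.6-fold and 143-fold the empty-vector level, and the levels follow the labels. The length used for Lef1 was 3549 bases in empty vector P2, 2955 in Lef1 P2 and 3024 in Lef1 P5. The expected reads were 48, 3585 and 5959, so the FPKM folds are larger than those of the reads. Lef1 P5 had 1.58 times the level of Lef1 P2. Reads of the introduced and the resident gene cannot be separated in a gene table.

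The comparison of Lef1 P2 with empty vector P2 has matched passage and differs, as labelled, by the introduced gene. Genes of the primitive and definitive endoderm list were far higher in Lef1 P2, while Pou5f1, Sox2 and Nanog stayed within 2-fold. The endoderm transcription factor gene Gata4 (Entrez gene 14463) was at 2.82 FPKM (2.26 to 3.48) in empty vector P2 and 66.0 FPKM (63.2 to 68.9) in Lef1 P2, 23.4-fold higher, Gata6 (Entrez gene 14465) at 2.24 and 46.3 FPKM and Sox17 (Entrez gene 20671) at 0.57 and 20.1 FPKM. The basement membrane collagen genes Col4a1 and Col4a2 were 18.5-fold and 20.03-fold higher, at 316 FPKM (311 to 320) and 195 FPKM (191 to 198). Lower genes included the cyclin genes Ccne1, from 122 to 43.8 FPKM, and Ccnd1, from 14.7 to 3.79 FPKM, and the growth regulator Myc, from 15.4 to 4.10 FPKM.

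In all, 691 genes were called higher and 194 lower of 10677 genes at 3 FPKM or more, and 689 and 193 of these had counting intervals that did not overlap. Counting noise alone gave at most 3 calls in 100 draws. The split depended on the scaling between libraries: 78.1% of the calls were higher with the deposited FPKM, against 62.3% (502 higher, 304 lower) with median-of-ratios, 62.5% (508 and 305) with TMM and 59.5% (462 and 314) with quantile scaling. The median of all measured genes was 0.11 as deposited and shifted by -0.14, -0.14 and -0.15 under these scalings, so list medians are given relative to it.

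Of the 24 measured endoderm genes, 19 were higher and 0 lower in Lef1 P2. The list's median lay 2.60 above that of all genes, at the 100th percentile of matched random lists, and its summed expression was 3561 FPKM against 815 FPKM. Besides those above, the laminin genes Lama1 (24.0 to 277 FPKM) and Lamb1 (31.6 to 330 FPKM), the collagen chaperone gene Serpinh1 (27.3 to 287 FPKM), the matrix protein gene Sparc (85.2 to 545 FPKM), the visceral endoderm receptor gene Cubn (2.68 to 32.96 FPKM), the growth factor receptor gene Pdgfra (0.91 to 14.7 FPKM) and Foxa2 (0.27 to 6.13 FPKM) were called higher. Each such pair gives the level in the second-named library first. The 5 members not called were Apoe, Hnf4a, Lrp2, Plat and Cpn1. In empty vector P2, 18 of the 24 were at 1 FPKM or more. The list shares 4 measured genes with other lists. Without them, 15 of 20 were higher, with a median 2.48 above all genes.

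**Figure D1:**
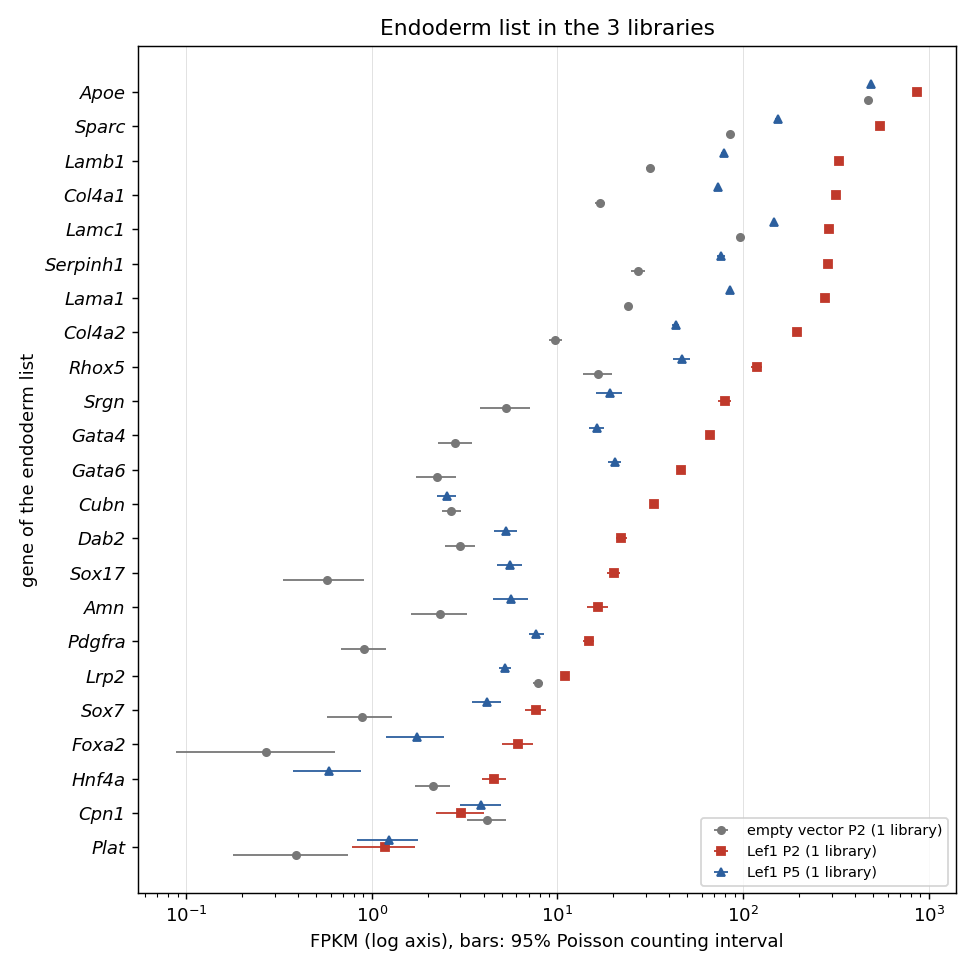
Levels of 23 of the 24 measured genes of the endoderm list in FPKM on a log axis, with 1 point per library (circle, empty vector P2; square, Lef1 P2; triangle, Lef1 P5) and bars for the 95% Poisson counting interval. Lef1 P2 has the highest level for most genes, such as Col4a1 at 316 FPKM, with Lef1 P5 in between at 73.4 FPKM and empty vector P2 at 17.0 FPKM, whereas Cubn in Lef1 P5 lies at the empty-vector level.

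Other lineage lists shared some of these genes. In the mesoderm list 5 of 13 measured genes were higher, among them Gata4 and Gata6, and in the primitive streak list 3 of 9 (Pdgfra, Foxa2 and Snai1). Neither median stood apart as deposited, at 0.26 and 0.32 above all genes (percentiles 71.9 and 75.8). The mesoderm list stood apart as higher with members measured at 3 FPKM (1.32, percentile 100) and with the mean of members (0.70, percentile 99.9), and the streak list with the mean (0.78, percentile 99.6), while its median ran from -0.14 with quantile scaling to 2.30 with members measured at 3 FPKM. The streak gene T was at 0.22 and 0.33 FPKM. In the trophectoderm and placenta list 7 of 22 genes were higher and 0 lower, including Ly6a, a stem cell surface antigen gene (3.14 to 108 FPKM), and the simple-epithelium keratin gene Krt8 (8.55 to 61.3 FPKM). Its median of 0.36 lay at percentile 95.5 as deposited, and the list stood apart as higher in 5 alternatives, with a pseudocount of 0.1 (0.70, percentile 99.7), median-of-ratios (0.41, 97.96), TMM (0.41, 98.1), CPM (0.47, 98.2) and the mean of members (0.69, 100). The trophectoderm factor gene Cdx2 was at 0.16 and 1.05 FPKM. The neuroectoderm list stood apart as lower (median -0.48, percentile 0.03), with Neurod1 (7.95 to 2.46 FPKM), Sox11 (5.35 to 1.76 FPKM) and Gbx2 called lower and the neural stem cell filament gene Nes higher (2.20 to 5.50 FPKM). Sox1 was at 1.06 and 0.88 FPKM.

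The formative and primed epiblast list also stood apart as lower (median -0.57, percentile 0), although as many of its 25 genes were called higher (3) as lower (3). The amino acid transporter gene Slc7a3 was lower (68.0 to 25.3 FPKM), as were Pou3f1 (6.26 to 2.29 FPKM) and Etv4, while Krt8, Krt18 (11.2 to 34.8 FPKM) and Otx2 were higher. Of the 37 genes for core and naive pluripotency, Tbx3 was called higher and Gbx2 lower, and the median of -0.34 did not stand apart (percentile 7.67). Pou5f1 was at 1135 FPKM in empty vector P2 and 704 FPKM in Lef1 P2, Sox2 at 254 and 192, Nanog at 160 and 167, Esrrb at 143 and 133, Klf4 at 66.2 and 65.7, Tfcp2l1 at 56.6 and 84.5 and Zfp42 at 362 and 279. Fgf5, a marker of primed epiblast, was at 0.09 and 0.05 FPKM.

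Target genes of beta-catenin/TCF went both ways. Of 29 measured targets 6 were higher, among them Snai1 (0.84 to 8.01 FPKM) and the Wnt antagonist gene Dkk1 (0.20 to 4.49 FPKM), and 3 were lower (Ccnd1, Myc and Notum). The median of -0.06 lay at percentile 12.2 as deposited, and the list stood apart as lower with median-of-ratios (-0.19, percentile 1.29) and TMM scaling. Axin2, a negative-feedback target of the pathway, was at 2.77 FPKM (2.27 to 3.34) and 5.89 FPKM (5.15 to 6.71), under the threshold on the log2(FPKM + 1) scale. The targets Sp5 and Cdx1 were at 0.16 and 1.28 FPKM in empty vector P2 and at 0.21 and 0.84 FPKM in Lef1 P2. Of 43 Wnt pathway components, Dkk1 and Dkk3 were higher and 0 lower (median -0.11, percentile 8.90). The related factor genes Tcf7 (28.0 and 22.03 FPKM), Tcf7l1 (27.2 and 17.8 FPKM) and Tcf7l2 (1.33 and 2.42 FPKM) and the beta-catenin gene Ctnnb1 (298 and 273 FPKM) were not called.

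In the glycolysis and hypoxia list 6 of 29 genes were higher, 0 lower and 23 not called (median 0.32, percentile 100). Those higher were the glycolytic enzyme genes Gpi1 (159 to 324 FPKM) and Aldoc (11.2 to 31.4 FPKM), the glucose transporter gene Slc2a3 (296 to 641 FPKM), the oxygen-sensing hydroxylase gene Egln1 (6.74 to 19.3 FPKM), the collagen prolyl hydroxylase gene P4ha1 (16.0 to 72.2 FPKM) and the angiogenic factor gene Vegfa (13.5 to 42.9 FPKM). In the stress list, with 26 of 34 genes not called, 6 were higher, such as the stress-response genes Chac1 (1.63 to 16.8 FPKM) and Ddit3 (8.55 to 45.0 FPKM), and 2 lower, the small heat-shock gene Hspb1 (828 to 334 FPKM) and the cystine transporter gene Slc7a11 (91.0 to 43.5 FPKM). The stress list's median of 0.09 lay at percentile 98.7, but no longer stood apart with quantile scaling (percentile 96.5), CPM (93.95) or members measured at 3 FPKM (96.5). In the cell cycle list the cyclin gene Ccnd2 was higher (0.49 to 5.68 FPKM) and Ccne1, Ccnd1 and Cdkn1c lower of 38 genes (median -0.22, percentile 34.2). Trp53 was the only p53-list gene called, at 190 and 93.1 FPKM (median of the 29 genes -0.29, percentile 4.31; the list stood apart as lower with a pseudocount of 5, percentile 2.44, and with CPM, percentile 2.23).

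Among 23 imprinted genes, H19 (1.07 to 15.1 FPKM), Igf2 (3.23 to 15.9 FPKM) and Sgce were higher and Phlda2 (74.0 to 16.0 FPKM), Snrpn (67.8 to 29.1 FPKM) and Cdkn1c lower (median -0.10, percentile 26.8). In the LIF/STAT3 and BMP/ID list 5 of 26 genes were higher, including Pramel7 (0.66 to 8.12 FPKM) and Msx2 (0.46 to 3.81 FPKM), and Gbx2 was lower (13.2 to 6.02 FPKM; median -0.14, percentile 25.5). The germline list had 4 of 28 higher, such as Taf7l (1.79 to 6.81 FPKM) and Slc25a31 (0.74 to 3.72 FPKM), and the egg coat gene Zp3 lower (4.47 to 1.56 FPKM; median 0.30, percentile 93.2, and 0.17 at percentile 98.1 with a pseudocount of 5). Of the 25 adhesion and epithelial-mesenchymal genes 6 were higher and 0 lower, led by Krt8 and Snai1 (median 0.15, percentile 94.9), and the list stood apart as higher with a pseudocount of 5 (percentile 98.8), quantile scaling (99.5), the mean of members (99.98) and members measured at 3 FPKM (98.4). Of 14 2-cell-like genes Pramel7 and Prnp were higher (median -0.18, percentile 4.51).

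Fibroblast and feeder-cell genes, read as a check for other cells in the culture, had 2 of 17 members higher, Ccn1 and Thbs1 (median -0.04, percentile 26.5). Replication-dependent histones (median -0.29, percentile 0.02) had 0 of 37 called, and the counts of 30 of them were not whole, so their levels are uncertain. Ribosomal protein genes stood apart as higher (percentile 100) with 0 of 79 called. Their median was 0.08 as deposited but -0.03 relative to all genes, and the 2579 most strongly expressed genes had a median of -0.13. None of the 53 oxidative phosphorylation genes was called (median -0.32, percentile 29.6; percentile 0.12 with CPM). Of the 26 long transcripts 1 was called, Dst (median 0.01, percentile 58.6).

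The highest ratios after Lef1 and Ly6a were those of Col4a2, Col4a1 and Gata4, followed by the retinol transporter gene Stra6 (0.36 to 20.6 FPKM), Gata6 and Sox17. The lowest were those of Apoo-ps, Gap43, Hsd17b14, Actn3, Phlda2, Sap25, Aard and Akr1b3. The growth-cone protein gene Gap43 was at 5.08 FPKM in empty vector P2 and not listed in Lef1 P2, at least 19.99-fold lower, and Hsd17b14, a hydroxysteroid dehydrogenase gene, was at 73.9 and 12.1 FPKM. The aldose reductase gene Akr1b3 was at 424 FPKM (412 to 435) and 101 FPKM (95.8 to 107), and the muscle alpha-actinin gene Actn3 at 11.4 and 1.70 FPKM. Aard was at 19.97 and 4.03 FPKM. Apoo-ps (at least 9.65-fold lower) and Sap25 (at least 10.3-fold lower) rest on few reads, and their counts were not whole. The counts of Akr1b3 were not whole either, so its level is less certain than its counting interval shows.

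The comparison of Lef1 P5 with empty vector P2 differs by the introduced gene and by passage, 5 against 2, and these cannot be separated because no empty-vector library of passage 5 was analysed here. Endoderm genes were again higher, by less than at passage 2. Gata6 was at 20.3 FPKM against 2.24 FPKM (1.73 to 2.86), 9.06-fold, Gata4 at 16.3 against 2.82 FPKM and Col4a1 at 73.4 against 17.0 FPKM. The chromatin protein gene Hmga2, active in embryonic and growing cells, was 6.28-fold higher (9.86 to 61.9 FPKM), above its 28.4 FPKM in Lef1 P2. Txnip, a glucose-responsive thioredoxin inhibitor gene, was at 82.8 FPKM (79.3 to 86.4) against 380 FPKM (372 to 387).

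In this comparison 142 genes were called higher and 130 lower of 10144, 142 and 127 of them with intervals that did not overlap. The higher share was 52.2% as deposited, and 58.1%, 57.0% and 59.5% with median-of-ratios, TMM and quantile scaling. More genes were lower than higher with a pseudocount of 0.1 (192 higher, 222 lower) and with CPM (269 and 276). The same held with a fold threshold of 1.5 (436 and 602), and the other settings had more higher calls. The median of all genes was -0.02.

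Of the 24 endoderm genes 12 were higher and 0 lower (median 1.28, percentile 100), with a summed expression of 1297 against 815 FPKM. Pdgfra was at 7.70 against 0.91 FPKM and Sox17 at 5.54 against 0.57 FPKM, whereas Cubn was at 2.53 against 2.68 FPKM. Foxa2 (1.74 against 0.27 FPKM) had a log2 ratio of 1.11 but lay under 3 FPKM in both libraries and was not called. Of the 20 members in no other list 9 were higher. The formative and primed list stood apart as higher here (median 0.21, percentile 99.9), with the Nodal antagonist gene Lefty2 (20.7 to 63.5 FPKM), the epiblast and anterior neural factor gene Otx2 (9.26 to 23.8 FPKM) and Krt8 higher and Pou3f1 lower (6.26 to 2.27 FPKM). None of the 37 pluripotency genes was called (median 0.06, percentile 67.3). Pou5f1 was at 1062 FPKM, Sox2 at 205, Nanog at 176, Esrrb at 146, Klf4 at 48.2, Tfcp2l1 at 66.9, Zfp42 at 386 and Fgf5 at 0.04 FPKM.

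Axin2 was called higher at 8.01 FPKM (7.15 to 8.94), 2.89-fold the empty-vector level, as was Snai1, while the 29 beta-catenin/TCF targets as a list did not stand apart (median 0.07, percentile 83.8). None of 43 Wnt components was called (median -0.08, percentile 7.86). Dkk1 was at 2.43 FPKM (1.80 to 3.20) against 0.20 FPKM (0.0545 to 0.512), a log2 ratio of 1.52, and was not called because both levels lie under 3 FPKM. Tcf7 was at 17.7, Tcf7l1 at 25.3, Tcf7l2 at 2.11 and Ctnnb1 at 325 FPKM. The target genes Sp5, T, Cdx1 and Cdx2 were at 0.52, 0.27, 1.44 and 0.20 FPKM, and none was called.

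Lists that stood apart as lower were the neuroectoderm list (median -0.56, percentile 0), with Neurod1 (7.95 to 2.53 FPKM) and the tau gene Mapt (4.08 to 1.52 FPKM) called lower and Sox1 at 0.43 FPKM, the germline list (-0.39, percentile 0), with the tubulin gene Tuba3a (25.4 to 8.67 FPKM) and the meiotic cohesin gene Smc1b (4.38 to 1.49 FPKM) called of 28, and the p53 list (-0.45, percentile 0), with Plk2 called of 29 (53.5 to 26.1 FPKM). The fibroblast list was lower too (-0.30, percentile 0.24), with Thy1 lower (15.7 to 7.21 FPKM) and Ccn1 higher (6.16 to 15.4 FPKM). Oxidative phosphorylation genes lay at percentile 0.25 with a median of -0.04 and 0 calls, and no longer stood apart with CPM (percentile 15.8) or the mean of members (4.32). The 2-cell-like list stood apart as higher (median 0.48, percentile 100), with Pramel7 (0.66 to 3.83 FPKM) and Calcoco2 (3.46 to 8.95 FPKM) called of 14. It did not stand apart with members measured at 3 FPKM (percentile 93.6), and 9 of its genes had counts that were not whole.

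The remaining lists did not stand apart as deposited. Imprinted genes had H19 (1.07 to 11.3 FPKM) and Igf2 (3.23 to 13.0 FPKM) higher and Cdkn1c (31.9 to 10.1 FPKM), Phlda2 (74.0 to 26.0 FPKM) and Slc22a18 lower (median 0.02, percentile 59.9). Medians and percentiles were 0.12 and 80.6 for the primitive streak list (Pdgfra and Snai1 higher), 0.08 and 76.8 for mesoderm (Gata4 and Gata6 higher) and 0.12 and 92.6 for trophectoderm (Krt8 and Ly6a higher). These 3 stood apart as higher in some alternatives: the streak list with CPM (0.38, percentile 98.9) and the mean of members (0.45, 99.7), mesoderm with the mean (0.48, 99.98) and members measured at 3 FPKM (0.36, 99.3), and trophectoderm with median-of-ratios (0.18, 98.1), TMM (0.18, 97.8), the mean (0.27, 99.9) and members measured at 3 FPKM (0.20, 97.52). They were -0.06 and 17.1 for LIF/STAT3 and BMP/ID targets (Pramel7 higher, Dusp9 lower), 0.05 and 56.3 for cell cycle (Cdkn1c lower) and 0.05 and 72.6 for adhesion genes (Krt8 and Snai1 higher). Glycolysis and hypoxia (0.13, percentile 96.2; 98.65 with CPM) had 0 calls and stress (0.10, percentile 91.6; 98.2 with the mean) had Chac1 higher. Histones (0.06, percentile 79.6), ribosomal proteins (0.09, percentile 77.5; 99.3 with CPM) and long transcripts (-0.04, percentile 32.1) had 0 calls.

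The highest ratios after Lef1 were those of Ly6a (11.3-fold), Gata6, H19, Hmga2, the peptidoglycan recognition gene Pglyrp1, Zfp966 and Sh2d4b. Pglyrp1 was at 4.77 FPKM and not listed in empty vector P2 (at least 9.16-fold), and Sh2d4b was at 6.61 against 0.35 FPKM. The lowest were Gm4724, Gm14434, Zfp967, Gap43 (5.08 to 0.25 FPKM), Txnip, Gm15441, the activin subunit gene Inhbb (9.0 to 1.49 FPKM) and Gm5091. Gm15441 (73.2 to 16.3 FPKM) overlaps Txnip on the other strand, and with the strand of counting not given their reads cannot be separated. Gm4724 (at least 102-fold lower), Gm14434, Zfp967 (at least 74.1-fold lower) and Zfp966 are zinc-finger genes of 1 cluster whose counts were not whole, so their single values are uncertain.

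**Figure D2:**
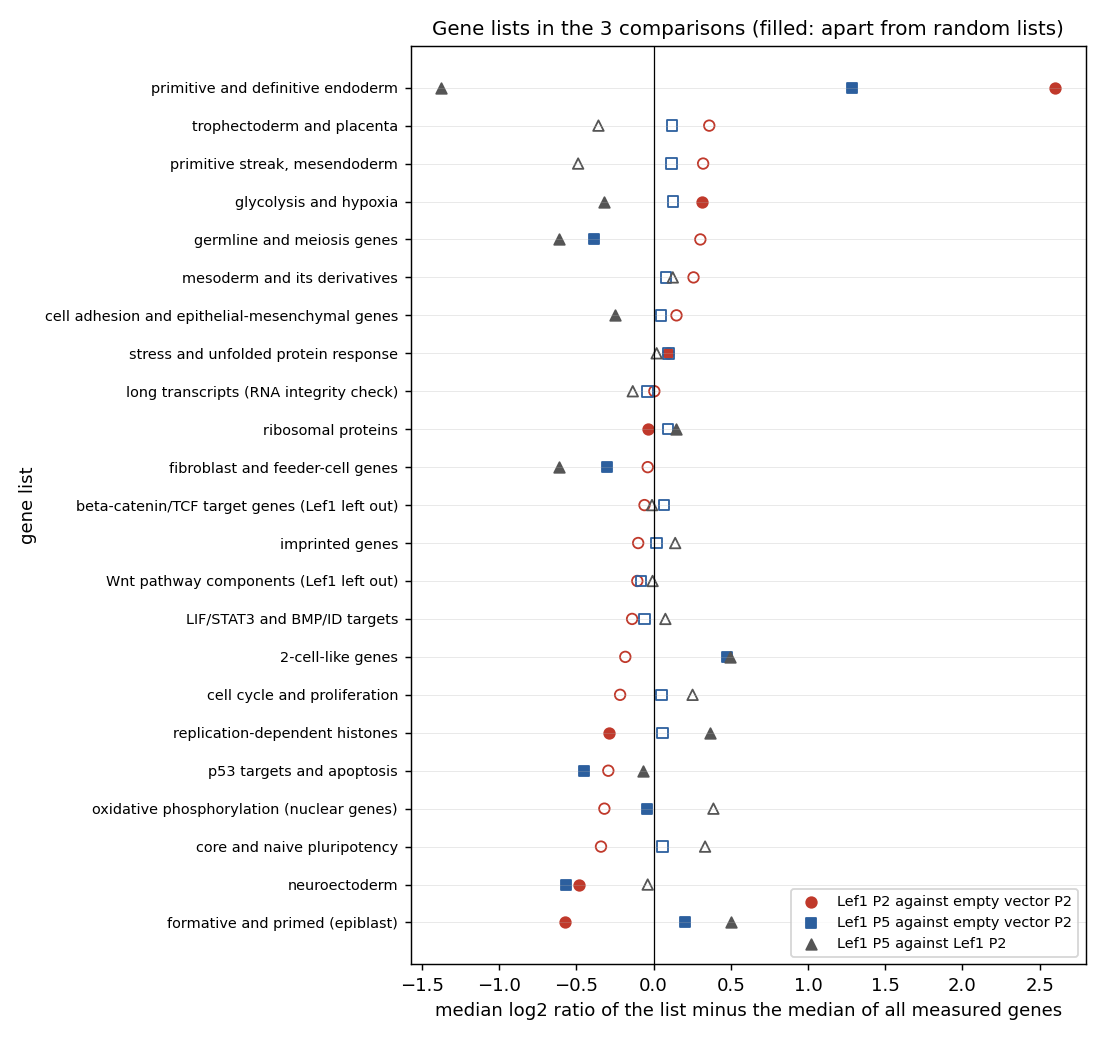
Median log2 ratio of each of the 23 gene lists minus the median of all measured genes (circle, Lef1 P2 against empty vector P2; square, Lef1 P5 against empty vector P2; triangle, Lef1 P5 against Lef1 P2), with 1 library per group. Filled marks stand apart from matched random lists; the endoderm list is farthest from 0, at 2.60, 1.28 and -1.37.

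The comparison of Lef1 P5 with Lef1 P2 sets a later against an earlier passage with the same introduced gene, with no empty-vector partner for the passage. Endoderm genes were lower at passage 5, and Ccnd1, Ccne1 and Myc were higher. Cubn was at 2.53 FPKM (2.24 to 2.85) against 32.96 FPKM (31.9 to 34.1), Gata4 at 16.3 against 66.0 FPKM and Col4a2 at 43.2 against 195 FPKM. Ccnd1 was at 15.3 against 3.79 FPKM, Ccne1 at 119 against 43.8 FPKM and Myc at 14.4 against 4.10 FPKM.

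There were 199 genes called higher and 727 lower of 10622, 199 and 724 of them with intervals that did not overlap. This split depended on the scaling even more: 21.5% of the calls were higher as deposited, 45.8% (380 higher, 450 lower) with median-of-ratios, 44.1% (368 and 467) with TMM and 40.8% (282 and 410) with quantile scaling. The median of all genes was -0.17 as deposited, shifted by 0.18, 0.17 and 0.19 under these scalings.

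Of the 24 endoderm genes 17 were lower and 0 higher (median -1.37, percentile 0). Lower lists also included glycolysis and hypoxia (5 of 29 lower; median -0.32, percentile 0), with P4ha1 (72.2 to 17.3 FPKM) and Vegfa (42.9 to 13.0 FPKM), and the germline list (8 of 28 lower, 1 higher; median -0.61, percentile 0), with the piRNA-pathway helicase gene Mov10l1 (7.53 to 1.52 FPKM) and Dpep3 (3.57 to 0.39 FPKM) lower and Zp3 higher (1.56 to 5.82 FPKM). The adhesion list (6 of 25 lower, 1 higher; median -0.25, percentile 0.485) had Krt8 (61.3 to 19.2 FPKM) and the tight-junction gene Cldn7 (23.9 to 8.22 FPKM) lower and the mesenchymal filament gene Vim higher (54.1 to 143 FPKM). The fibroblast list (median -0.61, percentile 0.03) had Timp3 lower (6.13 to 2.18 FPKM) and Vim higher, and did not stand apart with a pseudocount of 5, CPM or the mean of members (percentiles 3.89, 3.20 and 14.3). The p53 list (median -0.07, percentile 2.41) had Rb1 (11.9 to 4.57 FPKM) and Gdf15 (9.72 to 3.83 FPKM) lower and Trp53 higher (93.1 to 203 FPKM), and lay at percentile 2.74 with a pseudocount of 0.1 and 6.18 with CPM.

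The formative and primed list stood apart as higher (5 of 25 higher, 2 lower; median 0.50, percentile 100), with Slc7a3 (25.3 to 92.0 FPKM) and the Nodal antagonist gene Lefty1 (6.09 to 18.4 FPKM) higher and Krt8 and Krt18 (34.8 to 12.9 FPKM) lower. So did the 2-cell-like list (0.49, percentile 99.9), whose 1 called gene, Prnp, was lower (142 to 61.1 FPKM), and histones (0.36, percentile 100), with H2ac8 higher (1.12 to 5.16 FPKM) of 37. With members measured at 3 FPKM these 2 lists lay at percentiles 92.8 and 97.0. Ribosomal proteins lay at percentile 0 with a median 0.14 above all genes but -0.03 as deposited, and Rpl30 was higher (19.1 to 51.1 FPKM). The counts of H2ac8 and Rpl30 were not whole, so their levels are uncertain.

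Pluripotency genes did not stand apart (2 of 37 higher, Nr0b1 and Dppa2; median 0.33, percentile 76.3). The beta-catenin/TCF targets had Ccnd1, Myc and Notum higher and 4 lower, among them Vegfa and Jun (9.93 to 3.84 FPKM), with a median of -0.01 (percentile 71.0), and Axin2 was not called. Wnt components had 0 calls (-0.01, percentile 55.5). In the cell cycle list 5 of 38 genes were higher, including Ccnd1 and Ccne1, and Ccnd2 was lower (5.68 to 0.89 FPKM; median 0.25, percentile 58.3). The stress list had Slc7a11 (43.5 to 104 FPKM) and Hspb1 (334 to 734 FPKM) among 3 higher genes and the immediate-early gene Egr1 (17.2 to 3.84 FPKM) and Ddit3 (45.0 to 11.9 FPKM) among 6 lower genes (median 0.02, percentile 9.56).

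Imprinted genes had Snrpn (29.1 to 81.8 FPKM) and the placental gene Peg10 (43.9 to 95.05 FPKM) higher and Slc22a18 (6.07 to 1.24 FPKM), Sgce (6.87 to 2.76 FPKM) and Igf2r lower (median 0.14, percentile 80.7). Trophectoderm genes had 6 of 22 lower, such as Krt7 (7.01 to 0.83 FPKM), and Peg10 higher (median -0.36, percentile 3.83). The trophectoderm list stood apart as lower with a pseudocount of 0.1 (percentile 0.46), median-of-ratios (1.46), TMM, CPM (0.51) and the mean of members (0.97). Mesoderm had 4 of 13 lower (median 0.12, percentile 92.0), and its direction depended on the processing: it stood apart as lower with members measured at 3 FPKM (-0.72, percentile 1.52) and as higher with CPM (0.18, percentile 97.6). The primitive streak list had Foxa2 lower (-0.49, percentile 6.11) and the neuroectoderm list Msi1 lower (-0.04, percentile 61.2). LIF/STAT3 and BMP/ID targets had Fos and Msx2 lower (0.08, percentile 50.2), oxidative phosphorylation genes had 0 calls (0.39, percentile 71.3; 99.99 with CPM) and long transcripts had Lrp1 lower (-0.13, percentile 8.34; 0.43 with CPM).

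Among the highest ratios were those of the trypsin inhibitor gene Spink1 (3.96 to 31.1 FPKM), Sap25, Enox1 (2.27 to 13.0 FPKM), Apol6, Eprn (5.17 to 22.2 FPKM), the ribonuclease subunit gene Pop1 (6.42 to 26.4 FPKM) and Gm14308. The lowest were Cubn, Npcd (at least 83.4-fold lower), the parathyroid hormone receptor gene Pth1r (23.4 to 2.56 FPKM), Fam114a1 (33.3 to 4.04 FPKM), B4galnt2 (13.1 to 1.34 FPKM), the glycogen phosphorylase gene Pygl (17.4 to 2.19 FPKM), the proton pump gene Atp12a (5.37 to 0.14 FPKM) and Gm4724. Sap25, Apol6, Gm14308, Npcd, B4galnt2 and Gm4724 had counts that were not whole, so their levels are uncertain.

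Of the 691 genes higher in Lef1 P2, 84 were also higher in Lef1 P5. On the log2(FPKM + 1) scale 584 (84.5%) were within 2-fold of empty vector P2 there, and 525 (76.0%) lay above it. Their median log2 ratio was 1.32 at passage 2 and 0.31 at passage 5. Choosing genes by their ratio in Lef1 P2 against the shared empty-vector library can fix part of these values. After swapping the libraries' values within genes, 76.4% on average (70.5% to 82.1% in 1000 draws) were within 2-fold on that scale. Above empty vector P2 were 78.1% (71.4% to 84.0%), with a median of 0.45 (0.33 to 0.55) at passage 5. Swapping also puts values of Lef1 P2 in the place of empty vector P2, so these draws do not isolate the shared library. Of the 194 lower genes 34 were also lower and 160 were within 2-fold on the log2(FPKM + 1) scale. Their medians were -1.25 and -0.38, the second being -0.89 (-1.04 to -0.76) after swapping. Only Mlycd, the malonyl-CoA decarboxylase gene, was called in opposite directions, at 3.37, 8.81 and 1.03 FPKM in empty vector P2, Lef1 P2 and Lef1 P5. For genes higher in Lef1 P2 and lower in Lef1 P5, swapping gave 5.13 on average (at most 12), and independent lists would share 8.35. The empty-vector level of Mlycd lies just above the minimum of 3 FPKM.

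Both comparisons share the empty-vector library, which can create overlap. Swapping the libraries' values within genes gave 70.0 genes higher in both on average (at most 96 in 1000 draws) and 152 lower in both. Independent lists would share 9.12 and 2.34. Swapping also puts values of Lef1 P2 in the place of empty vector P2. The draws therefore do not give the overlap that comes from the shared library alone. The covariance of the log2 ratios was 0.10, against 0.15 after swapping and 0.01 from counting noise alone. Their correlation across genes was 0.42, and the 0.50 after swapping is fixed by construction. Part of any excess over independent lists may come from the shared library. Of the 691 genes, 401 were called lower in Lef1 P5 than in Lef1 P2, against 152 after swapping (at most 184) and 46.7 for independent lists, and this count shares the Lef1 P2 library.

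**Figure D3:**
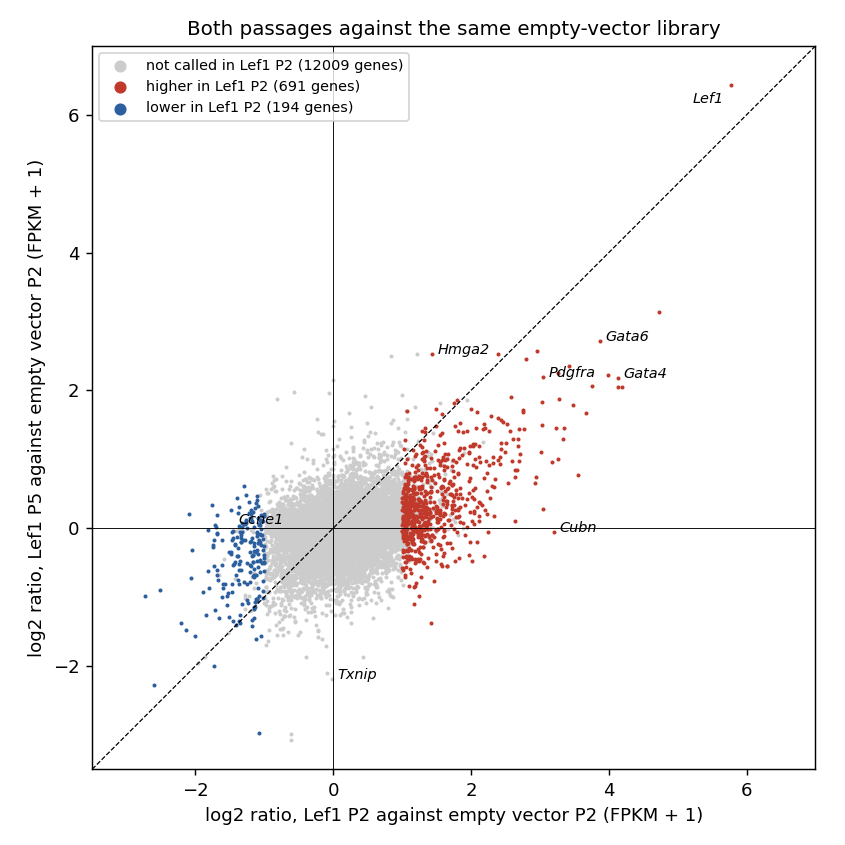
Log2 ratio of each measured gene in Lef1 P5 (vertical) against that in Lef1 P2 (horizontal), both against the same empty-vector library on the FPKM + 1 scale, with 1 library per group. The 691 genes higher and 194 genes lower in Lef1 P2 are coloured, and they lie closer to 0 on the vertical axis by their medians, 0.31 and -0.38, while Lef1 lies above the dashed line of equality. The coloured genes were chosen by their horizontal values, which by itself can place them closer to 0 on the vertical axis.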

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

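The results here were singled out because Lef1 P2 and Lef1 P5 differed from the same empty-vector library in opposite directions. With 1 library per group these differences were not tested.

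The formative and primed epiblast list had a median log2 ratio of -0.46 in Lef1 P2 and 0.19 in Lef1 P5, as deposited, and stood apart from random lists as lower in the first and higher in the second. Slc7a3, for example, was at 68.0, 25.3 and 92.0 FPKM in empty vector P2, Lef1 P2 and Lef1 P5, and Dnmt3b at 89.0, 65.6 and 145 FPKM, whereas Otx2 was higher in both Lef1 libraries and Pou3f1 lower in both.

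Mlycd had a log2 ratio of 1.17 in Lef1 P2 and -1.11 in Lef1 P5, with 64, 166 and 20 reads in the 3 libraries.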

How the results depend on the processing

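CPM as an alternative to FPKM and the endoderm list without shared members were added after the data were seen. With 1 library per group no replicate could be left out, and no paired analysis was possible because each group has 1 library. Filters on low values leave ratios and list medians as they are and were run for counts and overlaps, and keeping each row as its own feature was not run, as no symbol had more than 1 row. No named gene that was called changed sign, other called genes were not followed one by one, and no list that stood apart as deposited did so in the other direction, although the median of ribosomal proteins over all genes ran from -0.08 to 0.09 in Lef1 P2 and from -0.0950 to 0.20 between the Lef1 libraries. Of 69 list medians 16 changed sign across the settings, among them primitive streak in Lef1 P2 (-0.14 with quantile scaling). Of the list results 504 kept their side of the percentile limits, 37 stood apart only in an alternative, 1 did so in the direction opposite to its median as deposited and 13 lost it. Of the ratios of named genes 748 stayed within counting error and 356 moved beyond it. Of the counts of calls 36 stayed within 1.5 times the main count and 36 did not, and of the overlap values 18 stayed and 9 moved. The endoderm list stood apart in each of 10 settings, with a median over all genes of 1.89 to 3.26 in Lef1 P2, 0.74 to 1.51 in Lef1 P5 and -1.55 to -1.03 between them. Except where the construction shows it (a higher or lower threshold or floor), the cause was not tested. At this depth ratios that rest on few reads are imprecise, such as that of Dkk1, with 4 reads in empty vector P2 (0.0545 to 0.512 FPKM).

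Counts of calls are given as higher and lower where they moved. With a pseudocount of 5 they were 245 and 83 for Lef1 P2 against empty vector P2, 42 and 25 for Lef1 P5 against empty vector P2, and 101 and 180 for Lef1 P5 against Lef1 P2. With a pseudocount of 0.1, 222 genes were lower in Lef1 P5 than in empty vector P2. With at least 10 FPKM they were 357 and 121, then 67 and 49, and 358 lower in Lef1 P5 than in Lef1 P2. With a fold threshold of 1.5 they were 1864 and 855, 436 and 602, and 845 and 2116, and with a fold threshold of 4 they were 106 and 9, 17 and 7, and 5 and 42. With CPM they were 1225 higher in Lef1 P2, 269 and 276 in Lef1 P5, and 1275 lower in Lef1 P5 than in Lef1 P2. In Lef1 P2, 304 genes were lower than in empty vector P2 with median-of-ratios, 305 with TMM and 314 with quantile scaling. Between the Lef1 libraries the counts were 380 and 450 with median-of-ratios, 368 and 467 with TMM, and 410 lower with quantile scaling.

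The overlap of genes higher in both Lef1 libraries was 31 with a pseudocount of 5, 43 with at least 10 FPKM and 172 with CPM. That of lower genes was 56 with a pseudocount of 0.1, 6 with a pseudocount of 5, 16 with at least 10 FPKM and 59 with CPM. The covariance was 0.231 and 0.0388 with pseudocounts of 0.1 and 5. The log2 ratio of Lef1 was 6.41 and 4.43 in Lef1 P2 and 7.07 and 5.07 in Lef1 P5 with pseudocounts of 0.1 and 5, and 6.68 in Lef1 P5 with CPM. Between the Lef1 libraries it was 0.86 with median-of-ratios, 0.85 with TMM and 0.43 with quantile scaling.

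List medians below are over that of all genes. Lists that stood apart only in an alternative follow by setting. With a pseudocount of 0.1 this held for trophectoderm (0.70 in Lef1 P2, -0.67 between the Lef1 libraries), and with a pseudocount of 5 for germline (0.17), p53 (-0.25) and adhesion genes (0.16) in Lef1 P2. With median-of-ratios it held for trophectoderm (0.41 in Lef1 P2, 0.18 in Lef1 P5, -0.42 between them) and the beta-catenin/TCF targets in Lef1 P2 (-0.19), and with TMM for the same lists (0.41, 0.18, -0.42 and -0.19). With quantile scaling it held for adhesion genes in Lef1 P2 (0.29). With CPM it held in Lef1 P2 for trophectoderm (0.47), p53 (-0.31) and oxidative phosphorylation (-0.35), in Lef1 P5 for primitive streak (0.38), glycolysis (0.13) and ribosomal proteins (0.10), and between the Lef1 libraries for mesoderm (0.18), trophectoderm (-0.53), oxidative phosphorylation (0.43) and long transcripts (-0.0949). With the mean of members it held in Lef1 P2 for primitive streak (0.78), mesoderm (0.70), trophectoderm (0.69) and adhesion genes (0.41), in Lef1 P5 for primitive streak (0.45), mesoderm (0.48), trophectoderm (0.27) and stress genes (0.15), and between them for trophectoderm (-0.39). With members measured at 3 FPKM it held for mesoderm (1.32 in Lef1 P2, 0.36 in Lef1 P5), trophectoderm in Lef1 P5 (0.20) and adhesion genes in Lef1 P2 (0.23). Between the Lef1 libraries mesoderm, at 0.12 as deposited, stood apart as lower with members measured at 3 FPKM (-0.72), opposite to its call with CPM.

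Lists that no longer stood apart were stress genes in Lef1 P2 (0.15 with quantile scaling, 0.0673 with CPM and 0.0680 with members measured at 3 FPKM), p53 between the Lef1 libraries (-0.0491 with a pseudocount of 0.1 and -0.0455 with CPM), and fibroblast genes between them (-0.15 with a pseudocount of 5, -0.41 with CPM and -0.20 with the mean of members). The others were oxidative phosphorylation in Lef1 P5 (-0.0396 with CPM and -0.0175 with the mean of members) and, with members measured at 3 FPKM, 2-cell-like genes (0.22 in Lef1 P5 and 0.31 between the Lef1 libraries) and histones between them (0.0897).

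Median and mean of members, as deposited, differed in sign for LIF/STAT3 and BMP/ID targets (-0.0249 and 0.10) and 2-cell-like genes (-0.07 and 0.27) in Lef1 P2, and for histones (0.04 and -0.02) and cell cycle genes (0.03 and -0.0028) in Lef1 P5. In Lef1 P2 the medians of the beta-catenin/TCF targets (0.06), Wnt components (0.01), fibroblast genes (0.08) and imprinted genes (0.01) were above 0 as deposited and below that of all genes. The same held in the opposite direction between the Lef1 libraries for mesoderm (-0.04), LIF/STAT3 and BMP/ID (-0.09), imprinted (-0.03) and stress genes (-0.15).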

Other observations

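The lists of collagen-modifying, secretory and lysosomal genes, the retained shares, and the tests of scaling, counting error, fibroblast genes, single cultures, silent receptor genes and GC content were chosen only after the results were seen.

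Lists written after the called genes had been seen held genes higher in Lef1 P2 than in empty vector P2, although most of their members were not called. In a list of ER-to-Golgi transport genes 14 of 49 were higher and 0 lower, among them Kdelr2, a receptor that returns proteins to the endoplasmic reticulum (38.2 to 92.2 FPKM), and the cargo receptor gene Surf4 (39.5 to 115 FPKM). In a lysosome list 14 of 48 were higher, such as Hexa (24.2 to 87.0 FPKM), the cathepsin gene Ctsl (99.5 to 254 FPKM) and Cd63 (66.3 to 206 FPKM). Of 26 genes for collagen modification and basement membrane 8 were higher, including the prolyl hydroxylase gene P4ha2 (8.53 to 88.7 FPKM) and the perlecan gene Hspg2 (73.4 to 163 FPKM), and Fkbp10 and Col18a1 were lower. The medians lay 0.55, 0.65 and 0.48 above all genes, the lowest of the 3 at percentile 100. In Lef1 P5 against empty vector P2 the lists had 0, 2 and 2 higher genes and did not stand apart (percentiles 91.85, 79.99 and 46.9). As the lists were written for genes already seen to be called, these percentiles are no independent evidence.

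The 19 endoderm genes called in Lef1 P2 kept different shares of their excess in Lef1 P5. The median share was 23.3%, from -0.50% for Cubn, 11.9% for Dab2 and 15.8% for Lamb1 to 41.0% for Gata6, 48.6% for Sox7 and 49.2% for Pdgfra. A smaller share of the same mixture of endoderm-like cells could give equal shares, and the counting interval left out the median for 68.4% of the genes (13 of 19). Because the spread of such shares between cultures is not known with 1 culture per group, a smaller share of the same cells and a different composition cannot be told apart.

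Endoderm genes were higher in Lef1 P2, and 3 technical explanations were tested. Scaling between libraries left the list median at 2.55 or more over 3 rescalings, and 95.8% of the measured members (23 of 24) were higher with counting intervals apart, against at most 8.33% in 1000 draws with equal levels in both libraries, which argues against scaling and counting error as the cause. The summed level of the fibroblast genes Col1a1, Col1a2, Col3a1, Thy1 and Dcn was 0.608 times that of empty vector P2 (0.501 to 0.732; 17.2 and 10.5 FPKM, of which Thy1 was 90.9% and 91.1%) and that of the 4 without Thy1 0.592 times (0.387 to 0.874; 1.57 and 0.93 FPKM), against 4.37 times for the endoderm list, which argues against fibroblasts or feeder cells, although 16 of the 17 genes of the fibroblast list were at 1 FPKM or more in empty vector P2. The whole fibroblast list had a median of -0.04 over all genes in Lef1 P2, with 2 of 17 genes called higher, Ccn1 and Thbs1, and 0 lower. Differentiation of this single culture without a part of Lef1 stays open, since the number of cultures per group was 1, and it cannot be told apart from an action of Lef1. A candidate explanation, as a hypothesis only, is that Lef1 favours endoderm-like cells in this culture. Against a simple dependence on its level, Lef1 was 1.58 times higher in Lef1 P5 than in Lef1 P2, whereas 17 of the 24 endoderm genes were lower there and 0 higher. The Lef1 libraries also differ by passage. Further Lef1 and empty-vector cultures, with an empty vector of passage 5, would be needed to test the hypothesis.

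Weakly expressed genes were higher in Lef1 P2: by level, the median log2 ratio ran from 0.34 in the lowest group of 2579 genes to -0.13 in the highest, with a rho across genes of -0.29, whereas it was -0.03 and 0.02 in Lef1 P5 against empty vector P2 (rho 0.0549) and -0.39 and 0.13 in Lef1 P5 against Lef1 P2 (rho 0.318), so the trend belongs to the single Lef1 P2 library and enters both sets of calls made with it. The running median over GC content gave 0.00351 (bootstrap interval 0.000386 to 0.00581) of the gap of 0.48 between these groups. The rho was -0.30 without called genes. These values argue against GC content and against the called genes alone. Background reads could also raise weak genes. Library-scaled reads in 141 olfactory and vomeronasal receptor genes were 0.718 times those of empty vector P2 (0.680 to 0.759), but Olfr856-ps1, Olfr613 and Vmn1r58 held 91.0% of them, and in 131 silent receptor genes the ratio was 1.08 (0.847 to 1.39). Background reads, a mixture of cells and library preparation therefore stay open and cannot be told apart.

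Zinc-finger genes of 1 chromosome 2 cluster were called in opposite directions, with Gm4724 and Zfp967 not listed in Lef1 P5 and Zfp966 at 8.21 FPKM there. Of the called members 100% (9 of 9) had counts that were not whole, but so had 9 of the 10 members not called, against 9.90% of all genes. The summed library-scaled reads of the 19 genes were 1.18 times those of empty vector P2 (1.13 to 1.23), which argues against a loss of the whole cluster. Gm14308, Gm14434 and Gm4724 had near-equal expected reads in empty vector P2 (307, 307 and 308) and Lef1 P2 (185 each). In Lef1 P5 they had 796, 2.42 and 0. Zfp966 and Zfp967 had 19.6 and 223 in empty vector P2, 87.95 each in Lef1 P2, and 273 and 0 in Lef1 P5. The calls of these genes therefore cannot be read as changes of single genes. For the other called members, reads shared out differently between paralogs and a change within single members stay open and cannot be told apart. Counts that are not whole mark the cluster whether its members are called or not.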
